A study of Mus musculus with 6 samples.

How the data were processed

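The samples were 6 yolk sacs of mouse embryos at embryonic day 9.5, 3 labelled wild type and 3 labelled homozygous for a Tnrc6a gene-trap allele, and each sample's group was taken from its title. Per the labels' protocols, total RNA of each yolk sac was extracted with Trizol, labelled with biotin and hybridised to an Affymetrix Mouse Gene 1.0 ST array. The deposited table holds the authors' processed values of 35557 probe sets on a log2 scale, and all values analysed here come from it. MAS5 is the only tool named in the submitters' processing notes. The summary of probes, the background step, the normalization between arrays and the scale are not given in the sources used here. The scale was read from the values, which ran from 0.66 to 13.7 with none negative: as natural logs they would exceed what a scanner records. The 6 array medians were 5.22, 5.21 and 5.20 for wild types 1 to 3 and 5.22, 5.19 and 5.21 for mutants 1 to 3, so the values were used as deposited with no further normalization. How the authors' normalization affected differences between arrays stays unknown. No 2 arrays held the same values: at most 20 probe sets were identical between any pair.

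Probe sets were named through GEO's platform annotation of the array with 8 symbols brought up to date through their Entrez identifiers. It listed 21797 probe sets with 1 gene symbol, 1613 with several and none for 12147, and no gene was named for a result from a probe set with several except where that is stated. Chromosomes and gene order came from the RefSeq genes of GRCm38.p6; the array's own genome build is not given in the sources used here, so no coordinates are printed. Probe sets with a symbol and a mean log2 signal at or above the 30th percentile of these (4.29) were tested, which left 16387 probe sets of 14071 different single symbols. Before the data were examined, the design, the gene lists, the rule for named genes and the processing alternatives were fixed.

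Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, mutant minus wild type, no block), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. The study's design text names an unpaired two-sample test at 0.05, and this methods' t-test was run on the same values as an alternative. In the fit 4 residual degrees of freedom were joined by 3.47 prior degrees of freedom. Differences of single values were tested with exact two-sided permutation tests over 20 assignments of the labels, which cannot give a p below 0.1. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, against all other tested probe sets, with 1 probe set per gene (the brightest over all arrays) and Benjamini-Hochberg adjustment over 27 lists; camera with an estimated correlation and fry were run beside it. Of 28 lists, that of sex genes had fewer than 5 members and served only as a check. The lists covered cell types of the yolk sac (visceral endoderm, primitive erythroid cells, haematopoietic progenitors, macrophages, endothelium, mesenchyme), other tissues (trophoblast, decidua and parietal endoderm, embryo proper), microRNA factors, genes and let-7 targets, and pathways of metabolism, signalling, stress, growth and imprinting. Named genes were Tnrc6a and the 15 with the largest difference on each side among single-symbol probe sets with non-overlapping groups, first those past the adjusted threshold and then those at an unadjusted p under 0.05, without sex genes and without clone or predicted-gene names. In each list up to 4 members past the threshold were named, or the 2 with the lowest p where none passed.

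The script was tested on simulated data drawn around the real means, with 200 changed probe sets among 16387 in each of 20 draws of 3 against 3 arrays. Spreads were drawn at random from the variance distribution that limma fitted to all probe sets, not from each probe set's own values. The noise was normal, with no structure among the arrays. The rates below hold for that model and may differ in the real data. At an adjusted p under 0.05 it recovered 24.0% of changes of 0.5 on the log2 scale, 87.7% of changes of 1 and 98.8% of changes of 2, and called 0.0439% of unchanged probe sets. A list of the size of the endothelium list shifted by 0.2 was called in 20 of 20 draws, with 0 calls in 520 tests of other lists; the simulated genes varied independently of each other. Alternatives were quantile normalization, centring on array medians, other filters on dim probe sets, adding the probe sets without a symbol under the same percentile filter, an intensity trend with robust variances, array weights, the methods' t-test, the replicate number as a block, the Xist level as a covariate, leaving out each array, other list tests, and the mean of a gene's probe sets. After the data were seen, leaving out wild type 2 and the library labelled mutant 1 together and a fit of 1 probe set per gene were added. Sets of genes with microRNA seed sites were not tested, since no 3' UTR sequences were used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.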

Results

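Tnrc6a encodes GW182, a protein that binds Argonaute and links microRNAs to the deadenylation and decay of their target mRNAs. Total RNA from mouse yolk sacs at embryonic day 9.5 was profiled on Mouse Gene 1.0 ST arrays, with 3 arrays from wild-type littermates and 3 from embryos labelled homozygous for a Tnrc6a gene-trap allele. At this stage the yolk sac is a membrane of visceral endoderm, endothelium, mesenchyme and primitive blood cells that feeds the embryo. The comparison asks which mRNAs differ in this tissue when Tnrc6a is disrupted. The deposited log2 signals had medians between 5.19 and 5.22 on the 6 arrays, and the number of arrays limits the precision: the median standard error of a log2 fold change was 0.10, for a 95% interval of ± 0.24. Across the tested probe sets, which are not independent of each other, pairs of arrays correlated at r = 0.986 to 0.994 within a genotype and at r = 0.986 to 0.995 between genotypes. Xist, the RNA of the inactive X chromosome, was high in mutant 3, in wild type 1 (9.87) and in the library labelled mutant 1 (9.63). In the other libraries it read 3.58 to 3.90. The Y-linked genes Eif2s3y, Kdm5d and Uty showed the opposite pattern. Both sex patterns thus occurred in each genotype, but not in equal numbers. Per the labels' protocols each yolk sac came from an individual embryo. The genotype labels also carry the word mixed, which the sources used here do not explain.

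Tnrc6a itself was measured first, as a check of the labels. Its mean log2 signal was 8.11 ± 0.42 (SD, n = 3) in wild type and 6.11 ± 1.47 (SD, n = 3) in the mutants, a 3.98-fold lower level (log2 fold change −1.99, SE 0.65). The mutant libraries did not read alike. Mutants 2 and 3 read 5.33 and 5.20, which is 6.83-fold and 7.51-fold below the wild-type mean. The library labelled mutant 1 read 7.81, which is 1.23-fold below the wild-type mean and above wild type 2, at 7.62. Its Tnrc6a level goes against its label, and every direction given for the mutants below includes this library unless stated. The limma p for Tnrc6a was 0.0167 before and 0.999 after Benjamini-Hochberg adjustment. An exact two-sided permutation test gave p = 0.2, where 3 against 3 arrays cannot go below 0.1. The limma p was 7.83e-06 without the library labelled mutant 1 (log2 fold change −2.84) and missed 0.05 without wild type 1 (0.0518), wild type 3 (0.0512), mutant 2 (0.0588) or mutant 3 (0.0613). Leaving out the library labelled mutant 1 had to widen the difference, as this library was singled out by its Tnrc6a level. The position of the trap relative to the array probes is not given in the sources used here.

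**Figure D1:**
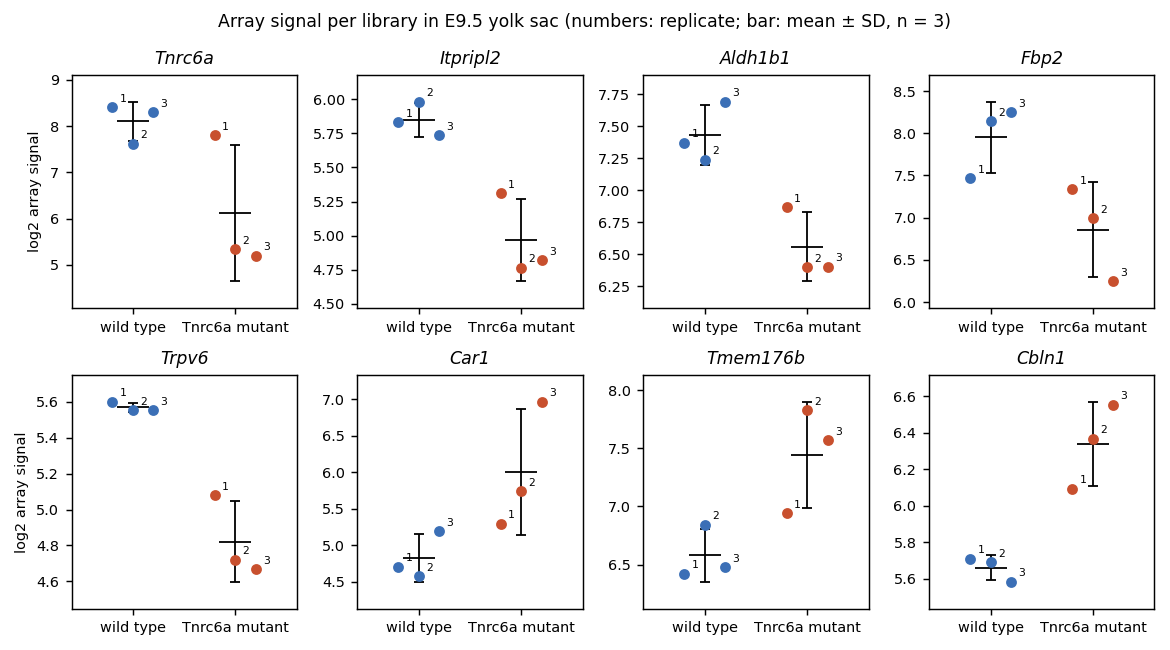
Log2 array signal (vertical axis) of Tnrc6a and of 7 of the named genes in each library, with the genotype on the horizontal axis, replicate numbers beside the points, and the mean ± SD (n = 3) as bars. For Tnrc6a the library labelled mutant 1 lies at 7.81, among the wild-type libraries, while mutants 2 and 3 lie at 5.33 and 5.20.

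No single gene passed the test between genotypes. The largest differences with non-overlapping groups were those of Car1 and Tmem176b, 2.26-fold and 1.82-fold higher in the mutants, and of Fbp2 and Rdh12, 2.14-fold and 2.08-fold lower. Among 16387 tested probe sets, limma called 0 at an adjusted p under 0.05 (lowest adjusted p = 0.999). At an unadjusted p under 0.05 there were 579 probe sets, 369 higher and 210 lower in the mutants, against 819 that chance gives. The methods' t-test put 627 probe sets under its threshold of 0.05, 386 higher and 241 lower, and 0 after Benjamini-Hochberg adjustment (lowest adjusted p = 0.451). The values of the genotypes did not overlap for 1401 probe sets (8.55%), where chance gives 10%. The count of 579 became 1372 without mutant 3, where the balance turned to 623 higher and 749 lower, and 1086 with array weights (637 higher and 449 lower). With the probe sets that lack a gene symbol added, under the same percentile filter on dim ones, the sides were nearly even, at 453 higher and 426 lower. Without wild type 2 and the library labelled mutant 1, an alternative chosen after seeing the data, limma called 1 probe set, that of Tnrc6a (adjusted p = 0.00285, against 0.108 to 1.00 for the lowest adjusted p in the other alternatives), and 1173 had an unadjusted p under 0.05. For Tnrc6a these libraries were the lowest wild type (7.62) and the highest mutant (7.81), so its difference had to widen. No conclusion is drawn from this call.

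By a rule fixed before the data were examined, 15 genes on each side were named from the probe sets with an unadjusted p under 0.05 and non-overlapping genotypes, and none of these 30 passed the adjusted test (adjusted p = 0.999 for each). Those higher in the mutants were led by Car1, a carbonic anhydrase, at a log2 difference of 1.18 (SE 0.40). Car1 was dim, at 4.57 to 5.19 in wild type. It read 5.29 in the library labelled mutant 1, 5.74 in mutant 2 and 6.96 in mutant 3. Tmem176b and Tmem176a, a pair of membrane proteins encoded side by side on chromosome 6, differed by 0.86 (SE 0.23) and 0.67 (SE 0.19). The metallothioneins Mt2 and Mt1, which bind zinc and copper, had wild-type means of 11.33 and 11.20 and differed by 0.55 (SE 0.15) and 0.52 (SE 0.13). Cbln1, a secreted synapse organiser, differed by 0.68 (SE 0.12) and Prkch, a protein kinase C, by 0.60 (SE 0.12). The extracellular matrix gene Hmcn1 differed by 0.55 at the named probe set, the highest of its 75, which ran from 0.047 and had a mean difference of 0.27 with overlapping groups (exact permutation p = 0.2). The carboxypeptidase gene Cpm and the cadherin gene Cdh15 both differed by 0.48. The others on this side were Zfp345 (0.67), Zfp738 (0.58), H2-Q4 (0.56), Aktip (0.54) and Gstm3 (0.48). The wild-type mean of Zfp345, 4.11, lay below the limit of the dim filter (4.29), which was set on the mean over all arrays. A further probe set of Gstm3 read 0.24, and the other probe sets of Zfp738 read 0.44 and 0.12.

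The genes lower in the mutants were led by Fbp2, a fructose-1,6-bisphosphatase of gluconeogenesis, at a log2 difference of −1.09 (SE 0.30). Rdh12, a retinal and retinol oxidoreductase, differed by −1.06 (SE 0.30), and Aldh1b1, a mitochondrial aldehyde dehydrogenase, by −0.88 (SE 0.17). Trpv6, an epithelial calcium channel, had the lowest unadjusted limma p (0.000305) of the tested probe sets, all of which have a gene symbol. It read 5.57 ± 0.027 (SD, n = 3) in wild type and 4.82 ± 0.22 (SD, n = 3) in the mutants. Glo1, the glyoxalase that clears methylglyoxal, differed by −0.70 (SE 0.20) and by −0.66 at its other probe set. Mogat1, a monoacylglycerol acyltransferase, differed by −0.63, and the nucleoside transporter gene Slc29a1 by −0.58. Itpripl2, which lies on chromosome 7 as does Tnrc6a, differed by −0.89 at the named probe set and by −0.024 at its other one. The rest were Trp53rka (−0.72), Klhdc4 (−0.72), Zscan10 (−0.61), Pllp (−0.60), Pkig (−0.59), Ppil1 (−0.59) and Ubash3a (−0.58).

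**Figure D2:**
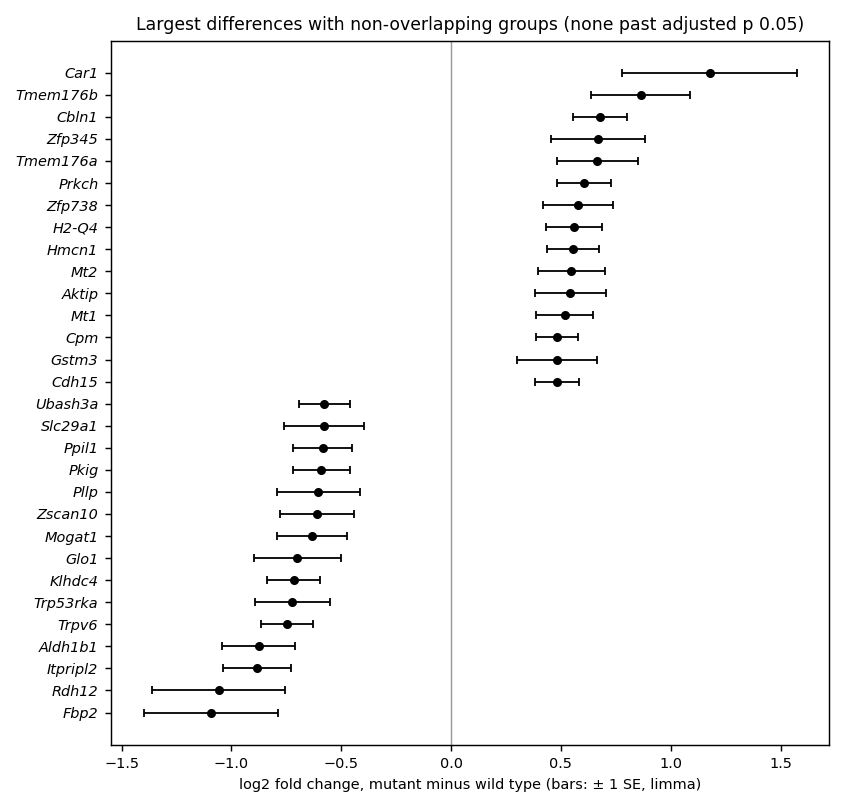
Log2 fold change (horizontal axis, mutant minus wild type, 3 arrays per genotype) of the 30 named genes, with bars of ± 1 SE from the limma fit. Differences run from −1.09 for Fbp2 to 1.18 for Car1, and none passed an adjusted p of 0.05.

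Among gene lists fixed before the data were examined, the primitive erythroid list was lower and the endothelium list higher in the mutants by 1 of the 3 list tests used. Of 27 lists tested with camera at its preset correlation, 7 passed an adjusted p of 0.05, 4 higher and 3 lower. None passed with an estimated correlation (lowest adjusted p = 0.846) or with fry (lowest adjusted p = 0.931), and in every list 0 members passed over all genes and 0 adjusted over the list alone. Primitive erythroid genes were lower for 26 of 26 members, with a mean log2 difference of −0.35 (adjusted p = 1.30e-12; adjusted p = 0.846 and unadjusted p = 0.151 with an estimated correlation). Hbb-y, an embryonic beta-like globin, differed by −0.25 (SE 0.092), and Alas2, the erythroid enzyme that starts haem synthesis, by −0.53 (SE 0.21). Mutant 2 held most of this shift: the list mean, relative to wild type, was −0.84 in mutant 2, −0.12 in the library labelled mutant 1 and −0.086 in mutant 3. Without mutant 2 the mean difference was −0.10 (adjusted p = 8.50e-05, the highest of the 6 fits that left out 1 library, from 1.50e-16), and in wild type it ran from −0.11 to 0.10.

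Endothelial genes were higher for 31 of 34 members, with a mean of 0.19 (adjusted p = 1.16e-09; adjusted p = 0.846 and unadjusted p = 0.0527 with an estimated correlation). Notch1, a receptor of arterial fate, read 7.01 ± 0.054 (SD, n = 3) in wild type and 7.28 ± 0.027 (SD, n = 3) in the mutants, and the angiopoietin co-receptor gene Tie1 differed by 0.28 (SE 0.089). The list mean was 0.061, 0.19 and 0.32 in the mutant libraries, the library labelled mutant 1 being the lowest, and −0.068, 0.084 and −0.017 in the wild-type libraries, so the groups overlapped. Mutant 3, the highest, also stood apart in the hypoxia and glycolysis list, at 0.50, and was the lowest library in the visceral endoderm list, at −0.14. Without mutant 3 the mean was 0.13 (adjusted p = 0.000221, the highest of the fits that left out 1 library, from 3.90e-12). Without wild type 2 and the library labelled mutant 1 the mean was 0.30. These were the highest wild type and the lowest mutant in the list, so the difference had to widen. Imprinted genes were higher for 19 of 22 members, with a mean of 0.18 (adjusted p = 0.000128; adjusted p = 0.846 and unadjusted p = 0.109 with an estimated correlation). Examples are Rtl1, a retrotransposon-derived gene of placental vessels, at 0.31 (SE 0.10), and Peg3, a paternally expressed zinc finger gene, at 0.26 (SE 0.087). The mean was 0.11 without wild type 3, 0.12 without mutant 3 and 0.29 without wild type 2 (adjusted p = 5.29e-08 to 0.0294 over the fits that left out 1 library). Wild type 2 stood apart in markers of other tissues, described below, and its imprinted list mean of 0.22 lay above those of the library labelled mutant 1, at 0.084, and of mutant 2, at 0.16.

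**Figure D3:**
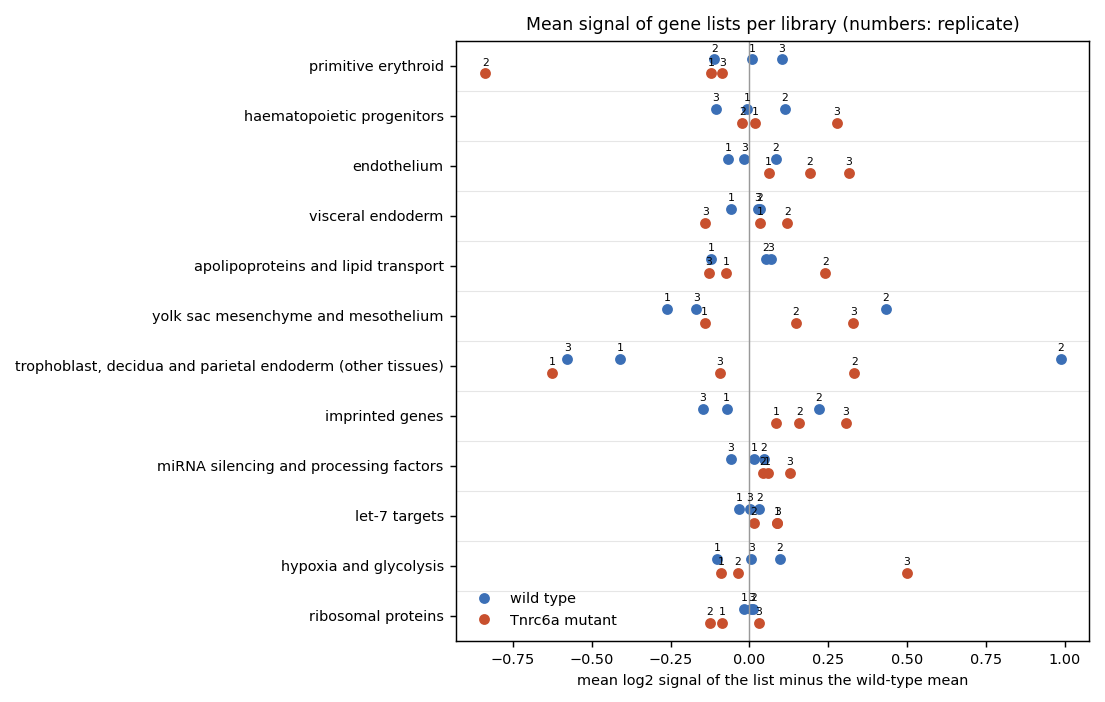
Mean log2 signal of 12 gene lists in each library, as the difference from the wild-type mean (horizontal axis), with wild type in blue, mutants in red and replicate numbers above the points. The erythroid list lies at −0.84 in mutant 2 and near the wild-type libraries in the other mutants, and the list of trophoblast, decidua and parietal endoderm lies at 0.99 in wild type 2.

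The other lists that passed shifted by less than 0.1 on the log2 scale over all arrays. Factors of microRNA silencing and processing, without Tnrc6a, were higher for 25 of 30 members, with a mean of 0.076 (adjusted p = 0.00906; adjusted p = 0.846 and unadjusted p = 0.162 with an estimated correlation). Mov10, an RNA helicase that associates with Argonaute, differed by 0.40 (SE 0.11) and Ago2, the slicing Argonaute, by 0.24 (SE 0.076) at its brighter probe set and 0.078 at the other. This call was lost without wild type 3 (adjusted p = 0.312) or mutant 3 (0.179), and the mean ran from 0.046 to 0.098 when 1 library was left out. Ribosomal protein genes were lower for 50 of 57 members, with a mean of −0.061 (adjusted p = 0.000324; adjusted p = 0.846 and unadjusted p = 0.251 with an estimated correlation), among them Rps13 at −0.18 and Rps15 at −0.14. That call was lost without mutant 2 (adjusted p = 0.0604, mean −0.028), the mean was −0.11 without mutant 3, and mutant 3 itself lay above every wild-type library, at 0.031. Genes of the unfolded protein and integrated stress responses were lower for 21 of 28 members, with a mean of −0.075 (adjusted p = 0.0163; adjusted p = 0.846 and unadjusted p = 0.235 with an estimated correlation), such as Trib3 at −0.42 and Ppp1r15a at −0.29. The call was lost without wild type 2 (0.351), the library labelled mutant 1 (0.0644) or mutant 3 (0.157), and the mean ran from −0.13 without wild type 1 to −0.023 without wild type 2. Genes of TGF-beta, BMP and Wnt signalling were higher for 25 of 35 members, with a mean of 0.094 (adjusted p = 0.0407; adjusted p = 0.941 and unadjusted p = 0.373 with an estimated correlation), such as the receptor genes Tgfbr2 at 0.35 and Fzd1 at 0.25. The call was lost without wild type 1 (0.492), wild type 3 (0.166), mutant 2 (0.0506) or mutant 3 (0.454), and the mean ran from 0.015 without mutant 3 and 0.021 without wild type 1 to 0.18 without wild type 2.

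Known targets of the let-7 microRNAs were higher for 18 of 27 members, with a mean of 0.063, and did not pass (adjusted p = 0.168); of 19 alternatives they passed in 1, without mutant 2 (adjusted p = 0.0170, mean 0.087; adjusted p up to 0.931 in the others). Stard13 differed by 0.24 (SE 0.085) and Fign by 0.22 (SE 0.085). Primary microRNA genes did not pass either, with 67 of 115 higher and a mean of 0.023 (adjusted p = 0.520), Mir212 and Mir679 having the lowest p at 0.16 and 0.17. They passed without wild type 1 (adjusted p = 0.00501, mean 0.055; up to 0.995 in the other alternatives), the mean was 0.00046 without wild type 2, and the direction in camera turned in 5 of 19 alternatives. Of the other GW182 and Argonaute genes, Tnrc6b and Tnrc6c differed by 0.034 and 0.15, and Ago1 and Ago3 by 0.10 and 0.0087. Visceral endoderm genes had a mean difference of 0.0047 (adjusted p = 0.966) with 18 of 33 higher; the mean ran from −0.053 without mutant 2 to 0.077 without mutant 3, where the list passed as higher (adjusted p = 0.0106; up to 0.996 in the other alternatives). Fgg, a fibrinogen chain, differed by −0.38 (SE 0.16) and Dpp4, a brush border peptidase, by 0.22 (SE 0.10). Apolipoproteins and lipid transport genes had 14 of 19 members higher and a mean of 0.013 (adjusted p = 0.392). This list turned lower without mutant 2 (mean −0.10) and passed as higher without mutant 3 (adjusted p = 0.00234, mean 0.084), with array weights (0.0263) and with the Xist covariate (0.0155), with adjusted p up to 0.943 in the other alternatives. Abca1, a cholesterol exporter, differed by 0.47 (SE 0.18). Fabp3, a fatty acid binding protein, differed by −1.07 (SE 0.69), with a signal of 9.02 in wild type 2 against 5.84 to 6.75 in the other libraries. Haematopoietic progenitor genes had 14 of 21 higher (mean 0.090, adjusted p = 0.0764), Mecom and Runx1, transcription factors of blood stem cells, at 0.36 and 0.32. This list passed without wild type 1 (adjusted p = 0.0341), wild type 2 (0.0386) or mutant 2 (0.00686) and without wild type 2 and the library labelled mutant 1 together (0.0362), with adjusted p up to 0.943 in the other alternatives, and its mean ran from −0.0030 to 0.15 when 1 library was left out.

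Markers of tissues that border the yolk sac varied between libraries of the same genotype. The list of trophoblast, decidua and parietal endoderm had a mean of 0.99 above the wild-type mean in wild type 2, against −0.41 and −0.58 in wild types 1 and 3 and −0.63, 0.33 and −0.095 in the library labelled mutant 1 and mutants 2 and 3. Prl4a1, a prolactin-like hormone, read 7.13 in wild type 2 and 3.51 to 5.14 elsewhere, while Slc38a4, an amino acid transporter, was highest in mutant 3, at 9.96, ahead of wild type 2, at 9.60 (difference 0.29, SE 0.36). The basement membrane list and the mesenchyme and mesothelium list were also highest in wild type 2, at 0.55 and 0.43 above the wild-type mean. Neither passed over all arrays (adjusted p = 0.392 and 0.168), and both did without wild type 2 (5.21e-09 and 2.72e-08, the lowest of the fits that left out 1 library, up to 0.857 and 0.991), with means of 0.24 and 0.33. Leaving out the highest wild type had to raise both means. Over all arrays, camera with an estimated correlation gave an adjusted p of 0.941 for each. Lama4 and Fn1 of the first list differed by 0.56 and 0.18, and Tbx3 and Wt1 of the second by 0.21 and −0.21. The hypoxia and glycolysis list lay at 0.50 in mutant 3 and at −0.10 to 0.10 in the other libraries (mean 0.12, 24 of 31 higher, adjusted p = 0.0738); the mean was −0.063 without mutant 3 and up to 0.23 when another library was left out, and the list passed in 6 of 19 alternatives (adjusted p from 0.000352 to 0.943).

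The remaining 11 lists did not pass, with adjusted p between 0.0738 and 0.990. The neighbours of Tnrc6a on chromosome 7 came nearest (19 of 29 lower, mean −0.048), with Slc5a11, a sodium-coupled transporter, at −0.37 and Ubfd1 at −0.13. Endocytic and lysosomal genes had 17 of 28 lower (adjusted p = 0.170), with the transferrin receptor gene Tfrc at −0.29 and the protease gene Ctsd at −0.14. Targets of p53 had 16 of 23 higher (adjusted p = 0.193), with the death receptor gene Tnfrsf10b at 0.28 and Pmaip1 at 0.17. Immediate early genes had 15 of 20 higher (adjusted p = 0.392), with Fos at 0.22 and Egr1 at 0.17. Cholesterol synthesis genes had 13 of 20 lower (adjusted p = 0.548), with the reductase gene Dhcr7 at −0.26 and Stard4 at 0.19. Macrophage and myeloid genes had 6 of 10 lower (adjusted p = 0.506), with Mpo at −0.22 and Laptm5 at 0.12. Histone genes had 18 of 28 lower (adjusted p = 0.718), with H4c9 at −0.20 and H2az2 at 0.21. Interferon response genes had 6 of 10 higher (adjusted p = 0.771), with Bst2 at −0.42 and Ifih1 at 0.12. Markers of the embryo proper had 13 of 19 higher (adjusted p = 0.575), with Tnnt2 at 0.12 and Sox10 at 0.11. Cell cycle genes had 19 of 35 higher (adjusted p = 0.990), with Ccnd1 at 0.20 and Birc5 at −0.093, and oxidative phosphorylation genes had 14 of 27 higher (adjusted p = 0.966), with Ndufa1 at −0.10 and Cycs at −0.14. Of these 11 lists, 3 passed when 1 library was left out: the neighbours of Tnrc6a without wild type 2 (adjusted p = 0.0228, up to 0.943 over the alternatives), endocytic and lysosomal genes without mutant 2 (0.00142, up to 0.943) and histone genes without wild type 3 (0.00225, up to 0.966). In the cell cycle and oxidative phosphorylation lists and in the trophoblast list (adjusted p = 0.787) the median lay above 0 while camera ranked the list lower, and the basement membrane list had a mean of −0.039, a median of 0.062 and a higher rank in camera.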

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

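The count of 0 changed probe sets was the same in 17 of 18 alternatives. Without wild type 2 and the library labelled mutant 1 it was 1, that of Tnrc6a. For this gene they were the lowest wild type and the highest mutant, so the difference had to widen. That alternative and the fit of 1 probe set per gene were chosen after seeing the data. The 30 other named genes stayed short of an adjusted p of 0.05 in all 525 values (lowest adjusted p = 0.111). None changed direction, but they were picked for non-overlapping groups. Their direction thus could not turn when arrays were left out or weighted, or with another variance model. The filter at the median removed some of them, such as Car1 and Trpv6, which have no value there. The number of probe sets at an unadjusted p under 0.05, 579 over all arrays, was 879 with probe sets that lack a gene symbol added under the same percentile filter on dim ones (more were tested, and chance gives 1244.5), 1086 with array weights, 1173 without the 2 libraries named above and 395 (without mutant 2) to 1372 (without mutant 3) when 1 library was left out, and stayed within 1.5 times of 579 otherwise. The Tnrc6a difference kept its direction in all 18 alternatives. It was −1.99 with an unadjusted p of 0.0866 by the methods' t-test (exact permutation p = 0.2). When 1 library was left out it ran from −2.84 to −1.54. The limma p was then over 0.05 without wild type 1, wild type 3, mutant 2 or mutant 3. It was 0.0200 without wild type 2 and 7.83e-06 without the library labelled mutant 1, where leaving out either had to widen the difference. The cause of the shifts in p and in the other counts here was not tested. Whether replicate numbers pair the arrays stays open. The deviations of same-numbered arrays from their group means correlated at 0.448, 0.146 and −0.107 across probe sets. Wild type 1 and mutant 1 were each other's best match, and mutant 2 correlated best with wild type 2. Wild type 2 correlated best with mutant 3 (0.236), and wild type 3 with mutant 1 (0.152). With the replicate number as a block, 0 probe sets passed, 727 had an unadjusted p under 0.05, the Tnrc6a p was 0.00617 and 7 lists passed; the unfolded protein list had an adjusted p of 0.0583 and oxidative phosphorylation (0.910) changed direction, while the hypoxia and glycolysis list passed (0.0221, against 0.0738 without the block). Of the alternatives fixed beforehand, a floor before log2 was not needed, as the table is on a log scale, the seed site sets were not run, and the methods' t-test gives no list values; nor does the fit of 1 probe set per gene. The tables hold no background signal, so what dim signals limit was seen only through the filters.

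The number of lists that passed, 7 over all arrays, was 0 with an estimated correlation and 0 with fry, 11 without the 2 libraries named above, 6 (without wild type 3 or mutant 3) to 11 (without wild type 2) when 1 library was left out, and 5 to 8 otherwise. With an estimated correlation the adjusted p was 0.846 for the erythroid, endothelium, imprinted, ribosomal, microRNA factor and unfolded protein lists and 0.941 for the TGF-beta, BMP and Wnt list. With fry it was 0.931 for the endothelium, imprinted and microRNA factor lists and 0.943 for the erythroid, ribosomal, unfolded protein and TGF-beta lists. These 2 tests allow for genes that vary together, which the preset correlation of 0.01 does only in part. The erythroid, endothelium and imprinted lists passed in the other 17 alternatives, all of which kept the preset correlation of 0.01. The estimated correlations were 0.869, 0.199 and 0.210 for these lists. The 17 passes therefore do not test that setting. With array weights the microRNA factor and TGF-beta lists had an adjusted p of 0.0792 and the unfolded protein list 0.108; with the Xist level as a covariate the microRNA factor list had 0.106 and the unfolded protein list 0.275. Without the 2 libraries named above the unfolded protein list had 0.525 and the ribosomal list 0.0580. When 1 library was left out, the adjusted p ran from 0.00142 to 0.312 for microRNA factors, 5.74e-06 to 0.0604 for ribosomal proteins, 0.000382 to 0.351 for the unfolded protein list and 0.000215 to 0.492 for the TGF-beta list. The 7 lists kept their direction in all alternatives, and the causes of the lost calls were not tested.

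Of the 20 lists that had not passed, 12 passed in at least 1 of their 19 alternatives: hypoxia in 6, mesenchyme in 5, haematopoietic progenitors in 4, apolipoproteins in 3, basement membrane and the neighbours of Tnrc6a in 2 each, and let-7 targets, primary microRNA genes, visceral endoderm, endocytic uptake, trophoblast and histones in 1 each. Lists that had not passed changed direction in 63 values. Cell cycle genes did so with quantile normalization (adjusted p = 0.648), median centring (0.981), the filter at the median (0.984), probe sets without a symbol added (0.838), an intensity trend (0.988), fry (0.945), the mean of a gene's probe sets (0.981) and without the 2 libraries named above (0.766). Oxidative phosphorylation did so with quantile normalization (0.800), the filter at the median (0.984), probe sets without a symbol added (0.838), an intensity trend (0.988), the Xist covariate (0.670), fry (0.945) and without those 2 libraries (0.244). The trophoblast list did so with the filter at the median (0.984), probe sets without a symbol added (0.838), the Xist covariate (0.959) and fry (0.945), and passed as higher without the 2 libraries (0.0140), which removes its highest wild-type array. Without those 2 libraries primary microRNA genes (0.0801), visceral endoderm (0.945) and embryo proper (0.309) also changed direction. The filter at the median turned the macrophage, interferon and immediate early lists (0.984 each), no filter turned visceral endoderm (0.970), array weights turned the macrophage list (0.999), and the Xist covariate turned primary microRNA genes (0.884) and embryo proper (0.959). With 1 library left out, the lists that changed direction in at least 1 such fit had an adjusted p of 0.00501 to 0.995 (primary microRNA genes), 0.0106 to 0.857 (visceral endoderm), 0.00234 to 0.783 (apolipoproteins), 0.00142 to 0.684 (endocytic uptake), 0.0975 to 0.874 (macrophage), 2.72e-08 to 0.991 (mesenchyme), 5.21e-09 to 0.857 (basement membrane), 0.106 to 0.684 (trophoblast), 0.205 to 0.960 (embryo proper), 0.000352 to 0.273 (hypoxia), 0.132 to 0.995 (cell cycle), 0.135 to 0.995 (cholesterol), 0.202 to 0.868 (oxidative phosphorylation), 0.00225 to 0.877 (histones) and 0.202 to 0.896 (interferon). The causes were not tested.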

Other observations

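Among genes chosen after their values were seen, adult beta-globin stood out. One of the 2 probe sets shared by Hbb-bs, Hbb-bt, Hbb-b1 and Hbb-b2 read 11.53, 11.42 and 11.32 in wild types 1 to 3 and 10.99 in the library labelled mutant 1, 10.30 in mutant 2 and 10.21 in mutant 3, a difference of −0.93 (SE 0.20, adjusted limma p = 0.999, exact permutation p = 0.1), and the other differed by −0.91. These beta-globin genes lie on chromosome 7, as does Tnrc6a, and whether a segment carried with the mutant allele affects them was not tested. On this chromosome 3.32% of tested genes separated the genotypes at an unadjusted limma p under 0.05, against 3.17% elsewhere. The embryonic globins Hba-x and Hbb-bh1 differed by −0.22 and −0.16, and for Hba-x mutant 3 read 12.74 against a wild-type mean of 12.78. Alpha-fetoprotein, transthyretin and apolipoprotein A-I, abundant products of the visceral endoderm, read 12.63, 12.68 and 12.44 in wild type and differed by −0.0054, 0.0069 and 0.0079. Hmcn1, which encodes the matrix protein hemicentin-1, is covered by 75 tested probe sets, and all 75 were higher in the mutants, 27 of them at an unadjusted p under 0.05. Their mean was 5.50, 5.76 and 5.49 in wild type and 5.75, 5.83 and 5.99 in the mutants, so the groups overlapped (difference 0.27, exact permutation p = 0.2). Of the 2 probe sets shared by the Dynlt1 dynein light chain genes on chromosome 17, both lower by 0.51, one read 11.17, 11.19 and 11.17 in wild type and 10.55, 10.91 and 10.56 in the mutants.

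The tests below were not in the design fixed before the data were examined. For the chromosome 17 tests by repeated probe sets and by spacing, the prediction was written before the test was run. The same holds for the count of lists over other splits. The other tests were chosen after the results were seen. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The genotypes gave 0 changed probe sets, a count that all 10 splits must reach, so this comparison decides nothing, the highest other count being 4. That count came from wild type 1 and mutants 1 and 3, the libraries with high Xist, against the rest, so that split is also one by sex. The genotypes gave 579 probe sets at an unadjusted p under 0.05, which 5 of 10 splits reached, the highest other count being 1883. They gave 7 lists, which 9 of 10 splits reached, the highest other count being 16. A split of wild type 1 and mutants 1 and 2 against the rest, and one of wild types 1 and 3 and mutant 1 against the rest (1861), gave more than 3 times the unadjusted count of the genotypes, which points to structure among the arrays other than genotype.

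The Tnrc6a level of the library labelled mutant 1, at 7.81, lay within the wild-type range. An exchange of labels with a wild-type library of the series would leave one of these near the level of mutants 2 and 3, and the lowest read 7.62. A probe set outside the lost part of the transcript would also read high in mutants 2 and 3, whose higher value was 5.33. RNA of trophoblast, decidua and parietal endoderm together is argued against by their list's value of −0.63 in this library, the lowest of the 6. That list averages 12 tested genes of these tissues, so RNA of decidua alone is not excluded. That this library may not be homozygous mutant stays open. Over 129 other genes that separated mutants 2 and 3 from wild type, its median position between wild type (0) and those mutants (1) was 0.322. The 95% interval, 0.242 to 0.401, came from resampling genes within this library, so it leaves out the spread between libraries. Genes were picked on the arrays that set the scale, so a wild-type library left out of that choice need not lie at 0. The same measure gave 0.547 for mutant 2 and 0.0616 for mutant 3, so library spread of that size decides nothing. Over all tested probe sets the library labelled mutant 1 correlated best with wild type 1 (r = 0.995, the highest of any pair). Its r was 0.992 with wild type 3 and with mutant 2, 0.987 with mutant 3 and 0.986 with wild type 2. Mutants 2 and 3 correlated least of all pairs (0.986), so correlation does not sort the arrays by genotype and cannot decide this. A biological difference, such as a mutant embryo that keeps a transcript through the trap, was not tested.

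The endothelium list was higher and the primitive erythroid list lower in the mutants by camera at its preset correlation, and neither passed with an estimated one (adjusted p = 0.846 for both) or with fry (0.931 and 0.943). Leaving out wild type 2, which holds markers of other tissues, decides nothing about the endothelial shift: this library was the highest wild type in the list, at 0.084, so the difference had to widen, from 0.19 to 0.23. Mutant 2 gave most of the erythroid shift, which was −0.10 without it against −0.35 with it. Fewer erythroid cells could raise the markers of all other cell types alike; endothelium minus visceral endoderm was 0.18 higher in the mutants, but with overlapping groups (exact permutation p = 0.2), and mutant 3 gave most of it, as the difference was 0.049 without this library. So this and a change in the vessels of the mutants cannot be told apart with 3 arrays each.

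Genes that separated the genotypes at an unadjusted p under 0.05 were more frequent on chromosome 17, at 38 of 706 tested genes (5.38%) against 3.07% elsewhere. Among the named genes they include Glo1, Ppil1, Zscan10, Slc29a1, Ubash3a and H2-Q4. Repeated probe sets of 1 gene do not account for it, as the adjusted one-sided Fisher p was 0.0213 with each gene counted once. A segment of another mouse strain could give such a cluster, though it would not be linked to the mutant allele, since Tnrc6a lies on chromosome 7, and stays open: a share of 0.607 of random draws of chromosome 17 genes lay as near to each other and 0.322 had as many (11) within 100 successive genes, but 21.6 of the 38 genes are expected from the share elsewhere and would hide a segment in the rest. The prediction written before the spacing test took spacing no nearer than random as speaking against a segment. It made no allowance for the genes expected from the share elsewhere, so that reading is not drawn here. In 3 of the 9 other splits a different chromosome was as over-represented, so an association with genotype as such is not shown.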
